A study of Mus musculus with 8 samples.

How the data were processed

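Total RNA from cultured primary palatal mesenchyme was labelled with biotin and hybridised to Affymetrix whole-genome mouse expression arrays, per the labels' protocols. The values deposited by the authors are log2 intensities, 1 per probe set and array, processed with RMA (background correction, quantile normalisation and probe summary) per the submitters' processing notes. The version of that tool is not given in the sources used here. The values ran from 3.21 to 15.18, with array medians between 6.90 and 6.96. They were used as deposited, with no further scaling. Probe intensities before RMA were not analysed here.

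Each sample was assigned to the mutant or control group from its title, and every column of the table matched 1 sample. Of 45101 probe sets, 64 were array controls, 34945 had 1 gene symbol, 932 had several and 9160 were not listed in the gene table used. Symbols were updated by Entrez identifier through an NCBI RefSeq table of the GRCm38.p6 assembly, which matched 34741 probe sets, and that table gave names only. Each gene was represented by the probe set with the highest mean over the 8 arrays, giving 18193 genes. Probe sets with several symbols or none were left out of the gene test. No genome build is named in the sources used here for the array values, so no coordinates are given.

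Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, mutant minus control, two-sided, no covariate), and p-values were adjusted with Benjamini-Hochberg over all genes, with a threshold of 0.05. SE values are limma's moderated errors. Gene lists, 42 in all with 985 genes, were fixed from the tissue, the gene and the metabolic question before the data were examined, as were the tests, the rule for named genes and most alternatives. Of the list genes 912 were measured, 4 of them through an older name. The 41 lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01, with the correlation estimated per list, and with fry. The list of Y-linked genes and Xist had fewer members measured and was used per array only. Means per array were compared with exact two-sided permutation tests, whose smallest p with 4 against 4 arrays is 0.0286.

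The named genes were Tgfbr2, then up to 12 genes per direction with the largest change among those past the threshold, with a gene name that is not a predicted model, no overlap between groups and a higher mean above the median of all probe sets (6.93). All 16 genes past the threshold met this rule. Up to 5 members with the smallest p were available to name from each list.

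Technical batches were sought in the array controls, since the labels give none: bioB for hybridisation, poly-A and 18S controls for labelling. The cre control probe sets report a hybridisation spike-in, not the transgene (13.64 against 13.63). The batch blocks, the fits within each hybridisation batch, the averaging of the closest arrays and the macrophage covariate were chosen after seeing the data. Alternatives fixed beforehand covered normalisation, probe set choice, dim genes, the variance model, array weights, thresholds and leaving out each array. Sex was not fitted as a covariate. The only female array was a control. With sex in the fit, the genotype difference would rest on the male arrays alone, as it does with that array left out.

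The procedure was tested on simulated data with 18193 genes and 4 against 4 arrays. It recovered 75% of 100 genes changed by 1 on the log2 scale and 95% of 100 changed by 2, with 6 false calls among 176, and called 0 of 40 unshifted lists. Genes varied independently in the simulation, unlike in these cultures.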

Results

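Gene expression was measured in primary mesenchymal cells grown from the palates of mouse embryos at embryonic day 13.5. The cells were collected after 2 passages in standard medium. Mutant embryos carried floxed Tgfbr2 alleles and Wnt1-Cre, which removes the floxed segment of this TGF-beta receptor gene in cranial neural crest cells and their descendants. Control embryos carried the floxed alleles without Cre. Each genotype had 4 Affymetrix whole-genome mouse expression arrays, and this number limits the precision of every value below. The labels count 4 samples per genotype without saying whether each came from its own embryo, so the p-values measure the spread between these samples, which may in part be technical. The study asked how disturbed TGF-beta signalling affects the metabolism of palatal mesenchyme, and mutant and control cells are its only comparison.

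The targeted gene Tgfbr2 was read by 3 probe sets, and none passed the test between genotypes. The brightest had a log2 intensity of 12.42 ± 0.47 (SD, n = 4) in mutant and 12.04 ± 0.40 (SD, n = 4) in control arrays. The difference was 0.37 (SE 0.27), with adjusted p = 0.558 in limma over all probe sets, and it was 0.30 and 0.44 within the hybridisation batches described below. Leaving out 1 array gave 0.25 without control 4 to 0.60 without mutant 4, and the macrophage covariate described below -0.02, with none past the threshold. The next read 7.69 ± 0.12 against 7.61 ± 0.07, and the dimmest 4.16 ± 0.06 against 4.09 ± 0.15 (SD, n = 4 each). Their differences were 0.08 (adjusted p = 0.699 in limma) and 0.07 (adjusted p = 0.774). Where these probes lie relative to the deleted segment is not given in the sources used here. A probe outside that segment checks nothing, so the genotype labels were not checked by these values, and every direction below rests on the labels.

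In mutant cells 12 genes fell and 4 rose among the 18193 tested, each by at least 1.5-fold. Cd200, a membrane glycoprotein that restrains myeloid cells, fell by 2.52 on the log2 scale (SE 0.25), from 9.26 ± 0.35 in control to 6.74 ± 0.46 in mutant arrays (SD, n = 4). Itgbl1, which encodes a protein related to beta integrins, fell by 2.43 (SE 0.29). Cthrc1, a secreted glycoprotein of remodelling connective tissue, fell by 2.19 (SE 0.24). Reep1, a protein that shapes the endoplasmic reticulum, fell by 1.77 (SE 0.13) and had the smallest adjusted p in limma, 0.0105. Tnfsf13b, the cytokine BAFF that sustains B cells, rose by 1.28 (SE 0.16), and the fibulin family matrix protein gene Efemp1 rose by 0.86 (SE 0.11).

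The other falls covered genes of unlike function. Log2 differences were -1.70 for Nrep, -1.58 for Glrb, the beta subunit of the glycine receptor, and -1.53 for Kcnk1, a potassium leak channel. Csrp2, a LIM domain protein of smooth muscle, fell by 1.40, from 12.31 ± 0.23 in control to 10.92 ± 0.31 in mutant arrays (SD, n = 4). The RNA-binding protein gene Mex3b differed by -1.29, the metalloprotease gene Adamts6 by -1.21 and the homeobox gene Meis1 by -1.04, and Limch1 fell by 1.00. Sbsn and the reticulon gene Rtn1 rose by 0.85 and 0.72. For all 16 genes the 4 arrays of one genotype lay beyond the 4 of the other. Their adjusted p in limma with Benjamini-Hochberg adjustment lay between 0.0105 and 0.0495. Of 14 further probe sets for 9 of these genes, 12 had the same sign, and 8 of the 14 had an unadjusted p under 0.05 in limma. The 2 with the opposite sign, for Limch1 and Meis1, were dimmer than the median probe set. So were all those with the same sign except probe sets of Nrep (mean 10.74) and Sbsn (mean 9.57). The 2 further probe sets of Meis1 read -0.00201 and 0.09. With the probe sets of each gene averaged, Meis1 read -0.31, Limch1 -0.50, Adamts6 -0.72, Tnfsf13b 0.69 and Reep1 -0.93, and of these 5 genes only Reep1 passed.

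**Figure D1:**
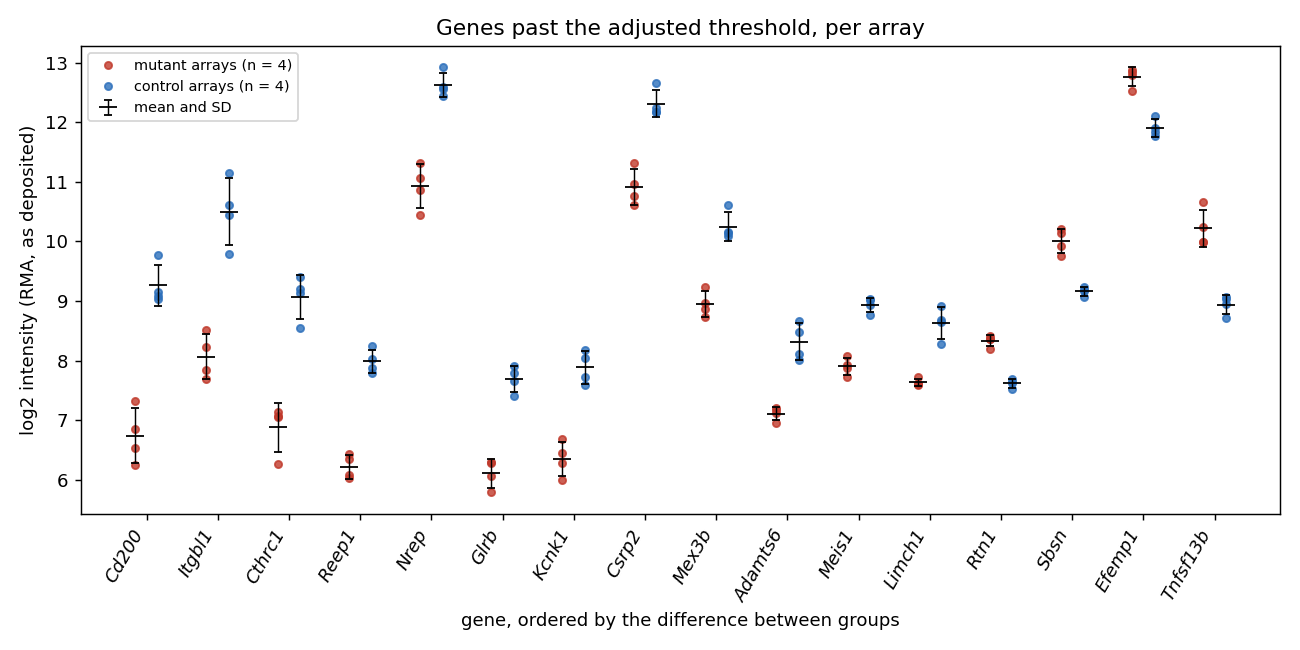
Log2 intensity (vertical axis) of the 16 genes past the adjusted threshold (horizontal axis), with points for the 4 mutant and 4 control arrays and bars for mean and SD. In each gene the groups do not overlap, from Cd200 with a difference of -2.52 to Tnfsf13b with 1.28.

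An unadjusted p under 0.05 was reached by 2826 genes, 1763 lower and 1063 higher in mutant cells. The arrays of the genotypes did not overlap for 1468 genes, 8.07% of those tested. The share by chance is 2.86% on average over all divisions of the arrays. Genes vary together in these cultures, and the share in single other divisions was not computed, so an excess over chance was not tested. The count of 16 moved with single arrays. It was 0 without mutant 1, mutant 2 or control 1, 1 without mutant 3 or control 3, and 2 without control 2. It was 31 without control 4 and 1316 without mutant 4. All 16 genes kept their sign in each of these fits, which was certain beforehand because the genotypes did not overlap for them. With each array centred on its median, 12 genes passed, 1 higher and 11 lower, against 4 and 12.

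Control probe sets divided the arrays in ways the labels do not mention. The bioB hybridisation controls read 6.34 to 6.52 on replicates 1 and 2 of both genotypes and 8.24 to 8.79 on replicates 3 and 4. With this hybridisation batch as a block 20 genes passed, including 14 of the 16. Within the first batch Cd200 differed by -2.71 and within the second by -2.34, Itgbl1 by -2.85 and -2.01, Cthrc1 by -1.81 and -2.57, Reep1 by -1.91 and -1.63, and Tnfsf13b by 0.94 and 1.62. The poly-A labelling controls set mutants 3 and 4 and control 3 (6.77 to 7.56) apart from the other arrays (8.53 to 9.21). With this labelling batch as a block only Cd200 (adjusted p = 0.000546) and Reep1 (adjusted p = 0.000427) passed in limma. Taken alone, the first hybridisation batch called 2085 genes and the second 0, where 947 had an unadjusted p under 0.05.

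Genes of amino acid synthesis and targets of the stress-response transcription factor ATF4 were lower in mutant cells. The median difference over 28 measured members was -0.63, and 25 were negative. None passed over all genes, and 16 fell when adjusted over the list alone. Slc7a3, a cationic amino acid transporter, fell by 1.63 (SE 0.30, list-adjusted p = 0.00919 in limma). The asparagine synthetase gene Asns fell by 0.72 (SE 0.14, list-adjusted p = 0.00919 in limma). Psph, the last enzyme of serine synthesis, and Slc1a4, a neutral amino acid transporter, differed by -0.63 and -0.68, both with list-adjusted p = 0.0118 in limma. The list passed camera with a preset correlation (adjusted p = 7.9e-10), with adjusted p = 0.753 with an estimated correlation. Its mean per array was 10.48 ± 0.24 in mutants and 10.99 ± 0.11 in controls (SD, n = 4, exact two-sided permutation p = 0.0286, the smallest 4 against 4 arrays can give, and 0.345 adjusted over the 41 lists). The list of p53 targets and cell cycle inhibitors, which did not pass camera, reached the same exact permutation p. The median difference was -0.72 within the first hybridisation batch and -0.43 within the second, and -0.45 with the mean of the macrophage markers described below as a covariate.

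Collagens and the enzymes that modify them were also lower, with a median of -0.45 over 31 members. No member passed over all genes; adjusted over the list alone 12 fell and 1 rose. Plod2, a collagen lysyl hydroxylase, fell by 1.56 (SE 0.30, list-adjusted p = 0.0218 in limma). The collagen gene Col8a1 fell by 1.03 (SE 0.22) and the prolyl hydroxylase subunit gene P4ha1 fell by 0.79 (SE 0.21), while Col14a1 rose by 1.13 (SE 0.27, list-adjusted p = 0.0249 in limma). The list passed camera (adjusted p = 1.4e-06), with adjusted p = 0.753 with an estimated correlation, and the medians were -0.51 and -0.32 within the hybridisation batches. Array means of the collagen list were 10.84, 11.17 and 11.08 in mutants 1 to 3, where the macrophage markers described below averaged 13.31, and 11.63 in mutant 4, where they averaged 11.19. With the macrophage mean as a covariate the collagen median was -0.19, and the list still passed camera.

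Other matrix genes had negative medians too. Of 26 elastic fibre and matrix glycoprotein genes (median -0.34), Efemp1 rose over all genes, and adjusted over the list alone 1 rose and 2 fell. The elastic fibre protein gene Fbln5 fell by 0.85 (SE 0.19) and the hyaluronan synthase gene Has2 fell by 1.26 (SE 0.34). Of 24 matrix proteases and inhibitors (median -0.43), 0 passed over all genes in limma and 3 fell adjusted over the list alone, with 12 at an unadjusted p under 0.05. Adamts12 fell by 1.28, Mmp12, the macrophage elastase, fell by 2.15 and the metalloprotease inhibitor gene Timp3 fell by 0.67. Both lists passed camera (adjusted p = 0.0114 and 0.0118), each with adjusted p = 0.753 with an estimated correlation. Medians within the hybridisation batches were -0.50 and -0.12 for the glycoproteins and -0.44 and -0.27 for the proteases, and with the macrophage mean as a covariate -0.40 and -0.23. The glycoprotein call ended without control 2, with dim genes left out and in the second hybridisation batch, and the protease call without mutant 3, in the second hybridisation batch and with the covariate; adjusted p for elastic fibre and matrix glycoproteins was 0.0663 without control 2 and for matrix proteases and inhibitors 0.0617 without mutant 3.

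Genes that TGF-beta is known to induce had a median of -0.41 over 28 members, of which 25 were negative. No member passed over all genes and 0 passed adjusted over the list alone; 10 had an unadjusted p under 0.05 in limma, all lower. Pmepa1, a feedback inhibitor of the pathway, differed by -1.04 (SE 0.31), the matricellular gene Ccn4 by -1.11 (SE 0.37), the lysyl oxidase gene Lox by -0.48 (SE 0.16) and Postn by -0.37 (SE 0.12). The list passed camera (adjusted p = 3.2e-05), with adjusted p = 0.753 with an estimated correlation; 15 of its members also stand on other lists. Its medians were -0.46 and -0.42 within the hybridisation batches. The median of the TGF-beta responsive genes was -0.64 without mutant 4, the mutant array lowest in the macrophage markers described below, and -0.15 with their mean as a covariate. Components of the TGF-beta pathway itself (28 members, median -0.15) did not pass (camera adjusted p = 0.611). With 1 array left out the median of TGF-beta pathway components ran from -0.26 without mutant 4 to -0.08 without control 4, and the list passed in none of these fits. The receptor antagonist gene Bambi differed by 0.75 (SE 0.22), Tgfbr1 by 0.41 (SE 0.13) and Smad3 by -0.24 (SE 0.09), with 0 of 28 past the limma test over all genes or adjusted over the list alone and 4 at an unadjusted p under 0.05.

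Cell cycle genes were slightly lower. The 30 genes of G1/S and DNA replication had a median of -0.25, with 12 lower at an unadjusted p under 0.05 and 0 past the limma test over all genes or adjusted over the list alone. The replication helicase gene Mcm2 differed by -0.53 (SE 0.12) and the licensing factor gene Cdc6 by -0.66 (SE 0.17). The 29 genes of G2/M and mitosis had a median of -0.19, with 5 lower at an unadjusted p under 0.05 and 0 past either adjustment in limma. Camera gave adjusted p = 3.6e-05 and 0.0204, and each had adjusted p = 0.753 with an estimated correlation. Medians within the hybridisation batches were -0.16 and -0.34 for G1/S, whose call ended in the first batch alone, and -0.15 and -0.17 for G2/M, and with the macrophage mean as a covariate -0.34 and -0.31. The mitotic call ended with quantile normalization, with each array centred on its median and with dim genes left out. It also ended with the labelling batch as a block and without mutant 3, mutant 4, control 1 or control 2, where the medians for cell cycle, G2/M and mitosis were -0.11, -0.12, -0.08, -0.10 and -0.16.

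Hypoxia-induced genes had a median of -0.42 over 20 members, 7 of which stand on other lists. None passed over all genes; adjusted over the list alone 2 fell. Ankrd37 fell by 0.59 (SE 0.15) and P4ha1 fell by 0.79 (SE 0.21). Camera gave adjusted p = 0.0118, with adjusted p = 0.753 with an estimated correlation. Within the hybridisation batches the medians were -0.46 and -0.39, and with the macrophage mean as a covariate -0.24. The call ended without mutant 3, where the median of the hypoxia-induced genes was -0.29, with dim genes left out, and in the second hybridisation batch alone.

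Metabolic lists other than amino acid synthesis did not pass camera, and 0 of their members passed over all genes in limma, where 2826 genes had an unadjusted p under 0.05. Medians were -0.16 for glycolysis and glucose uptake (23 members, adjusted p = 0.184), 0.05 for the pentose phosphate pathway (9, 0.936), -0.05 for the TCA cycle (23, 0.522) and 0.04 for oxidative phosphorylation (40, 0.116). Lipid genes had medians of 0.01 for cholesterol synthesis (20, 0.673), -0.08 for fatty acid and triglyceride synthesis (26, 0.673), 0.02 for lipid droplets and lipolysis (28, 0.716), -0.04 for fatty acid oxidation (27, 0.979) and 0.04 for adipogenic genes (18, 0.249). Median and mean differed in sign for the pentose phosphate pathway (mean -0.00174), and median and camera direction for fatty acid oxidation. Adjusted over the list alone, 1 lipid gene passed: Me1, a cytosolic source of NADPH, fell by 0.61 (SE 0.13, list-adjusted p = 0.0285 in limma). The hormone-sensitive lipase gene Lipe differed by 0.46 (SE 0.11), the cholesterol exporter gene Abca1 by 1.16 (SE 0.40), and the lactate dehydrogenase genes Ldha and Ldhb by -0.33 (SE 0.12) and 0.55 (SE 0.19). The list of glycolysis and glucose uptake passed camera without mutant 4 or without control 4 (medians -0.20 and -0.17; adjusted p from 0.00379 to 0.922 over its alternatives), and oxidative phosphorylation passed without mutant 4 (median 0.07; adjusted p from 0.0490 to 0.753). Within the hybridisation batches the medians were -0.27 and -0.10 for glycolysis and 0.06 and 0.02 for oxidative phosphorylation.

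Interferon-induced genes were higher in mutant cells, with a median of 0.63 over 25 members, 24 of them positive. None passed over all genes, and 2 rose adjusted over the list alone: the ISG15 protease gene Usp18 rose by 1.57 (SE 0.34) and the antiviral gene Rsad2 by 0.76 (SE 0.18), both with list-adjusted p = 0.0289 in limma. Camera gave adjusted p = 1.3e-08, with adjusted p = 0.753 with an estimated correlation. The median was 0.12 within the first hybridisation batch and 1.00 within the second, where control 4 had the lowest array mean of the list (8.74) and mutant 4 the highest (10.43). Without control 4 the median for interferon-induced genes was 0.38, and with the macrophage mean as a covariate it was 0.59.

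Markers of macrophages and other leukocytes were bright on every array: 20 of the 21 lay above the median probe set on all 8. The median difference was 0.81 and all 21 were positive, yet 0 passed over all genes or adjusted over the list alone, and 5 had an unadjusted p under 0.05 in limma. The fractalkine receptor gene Cx3cr1 differed by 1.67 (SE 0.44), Aif1 by 1.74 (SE 0.56), Ptprc, the leukocyte antigen CD45, by 1.23 (SE 0.48) and Cd52 by 0.66 (SE 0.18). Camera gave adjusted p = 6e-06, with adjusted p = 0.753 with an estimated correlation. The list mean was 12.78 ± 1.06 in mutants and 11.91 ± 0.82 in controls (SD, n = 4, exact two-sided permutation p = 0.2, 0.333 adjusted over 10 marker lists). It was 13.31 in mutants 1, 2 and 3, 11.19 in mutant 4, 12.50 and 12.72 in controls 1 and 2, and 11.27 and 11.14 in controls 3 and 4. The medians were 0.63 and 0.94 within the hybridisation batches, and 0.50 for macrophage and leukocyte markers without control 4 and 1.36 without mutant 4. With the macrophage mean as a covariate 55 genes passed, including all 16.

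**Figure D2:**
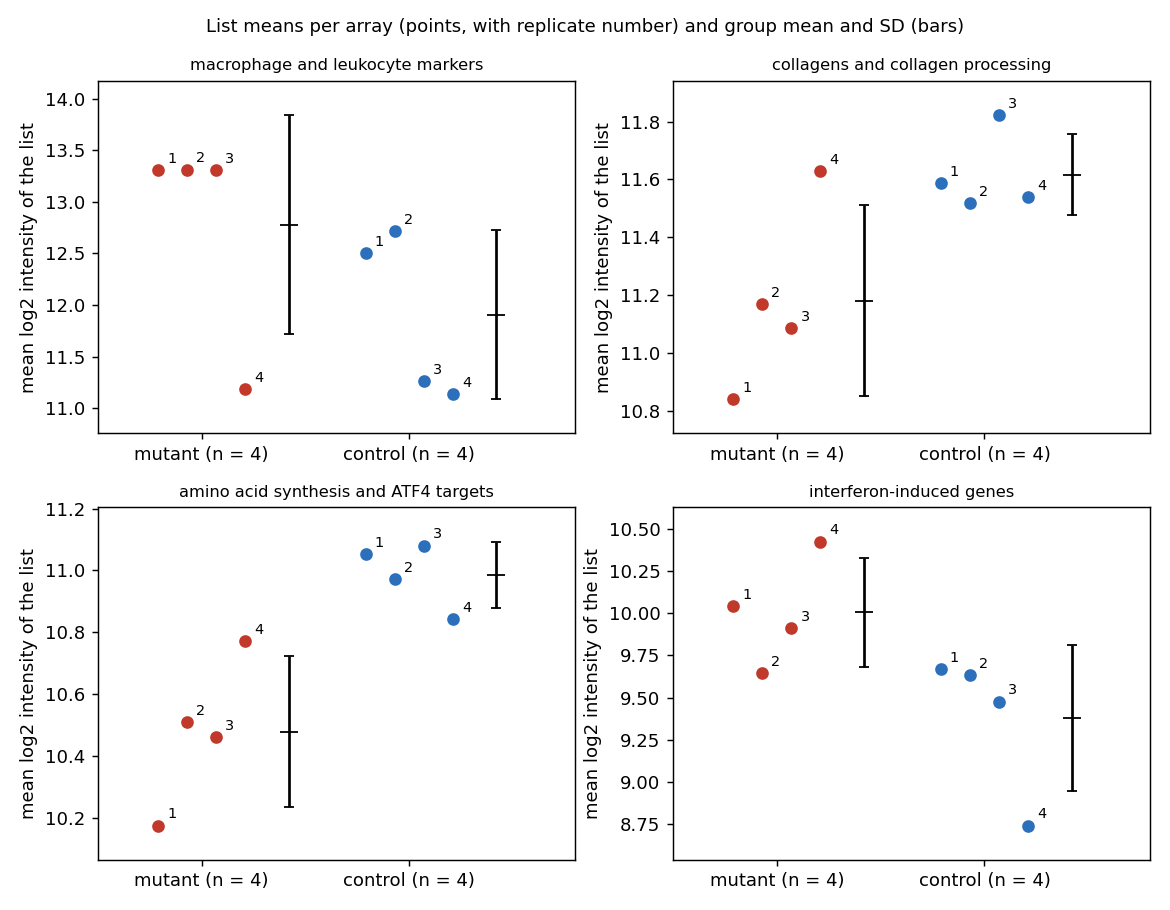
Mean log2 intensity per array (vertical axes) of 4 gene lists in mutant and control arrays, with replicate numbers beside the points and bars for the group mean and SD. Mutants 1 to 3 lie near 13.31 on the macrophage markers and mutant 4 at 11.19, and on the ATF4 list all 4 mutants lie below all 4 controls.

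Markers of the other cell types a dissected palate could hold did not pass camera: epithelial (median 0.04, adjusted p = 0.225), endothelial (0.03, 0.661), skeletal muscle (-0.01, 0.936), neuronal and glial (0.02, 0.522), erythroid (0.05, 0.184), pericyte (-0.05, 0.396), chondrocyte (-0.09, 0.225), osteoblast (-0.31, 0.0700) and tendon (-0.03, 0.249). Members above the median probe set on all 8 arrays numbered 4 of 23 epithelial, 6 of 18 endothelial, 10 of 23 muscle, 5 of 18 neuronal and 1 of 12 erythroid. They were 6 of 11 for pericyte, 7 of 20 for chondrocyte, 8 of 14 for osteoblast and 11 of 15 for tendon. Where most members were dim, a small median says little about that cell type. The neuronal mean was -0.10, opposite in sign to its median, and the camera direction for muscle was opposite to its median. Dlx5, a homeobox gene of bone and jaw formation, fell by 1.13 (SE 0.15, list-adjusted p = 0.000888 in limma over the osteoblast list, adjusted p = 0.0607 over all genes). Adjusted over the list alone, the cartilage regulator Sox9 fell by 1.04 (SE 0.23), the pericyte marker Cspg4 fell by 0.72 and the erythropoietin receptor gene Epor rose by 0.40. By the same adjustment the tendon regulators Scx and Mkx differed by -0.99 (SE 0.20) and -1.71 (SE 0.44). On that list Col14a1 rose by 1.13 (SE 0.27, list-adjusted p = 0.0206 in limma). None passed over all genes in limma. Within the hybridisation batches the medians were -0.51 and 0.01 for osteoblast genes and -0.42 and 0.11 for tendon genes. Osteoblast genes passed camera without mutant 3 or without control 4 (medians -0.29 and -0.38; adjusted p from 0.00136 to 0.922 over the alternatives), and tendon genes passed without control 4 (median -0.27; adjusted p from 0.00263 to 0.830).

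**Figure D3:**
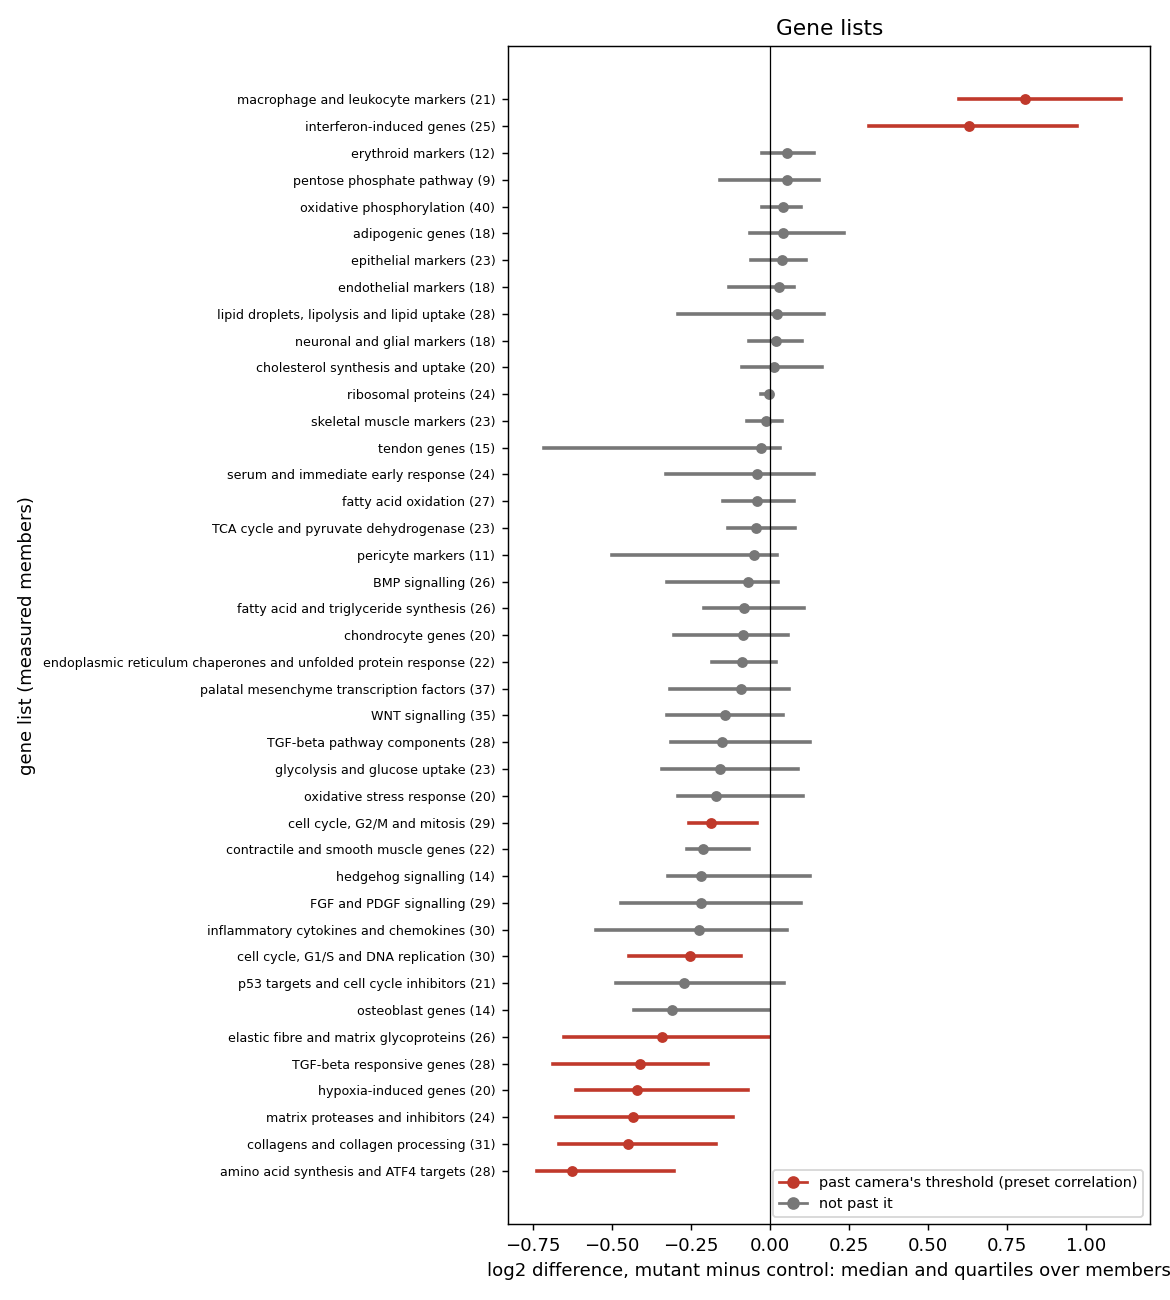
Median and quartiles of the log2 difference, mutant minus control (horizontal axis), over the measured members of 41 gene lists (vertical axis, members in brackets). Coloured lists passed camera with the preset correlation, 2 above zero and 8 below, from macrophage markers at 0.81 to amino acid synthesis and ATF4 targets at -0.63.

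In all, 10 of the 41 lists passed camera with the preset correlation, and 0 did with an estimated correlation or in fry. Estimated correlations over the 10 lists ran from 0.21 for elastic fibre and matrix glycoproteins to 0.93 for macrophage and leukocyte markers. The preset was 0.01, far below these estimates, so the calls at the preset rest on that assumption. Fry's test for change in either direction passed 2, the ATF4 and osteoblast lists (adjusted p = 0.0400 each). Within the labelling batches the 8 lower lists had medians from -0.70 to -0.02 and the 2 higher lists from 0.46 to 1.21. Without mutant 4 the number of lists passed was 18.

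RNA quality measures gave no detectable difference between genotypes. The log2 ratio of 3' to 5' signal was -0.14 ± 0.02 and -0.11 ± 0.03 for Gapdh (exact two-sided permutation p = 0.2) and 0.12 ± 0.03 and 0.14 ± 0.01 for beta-actin (exact two-sided permutation p = 0.171; SD, n = 4). Within the genotypes, mutants 1 and 2 and controls 1 and 2 were the most alike. The SD of their differences over genes was 0.21 and 0.19, against 0.30 to 0.58 and 0.38 to 0.52 for the other pairs of arrays of a genotype. Array values carry no counting noise to test this against, and they were kept as separate samples. With each of these pairs averaged to 1 sample, 0 genes passed in limma (1612 with an unadjusted p under 0.05). Of the 10 lists 9 passed, the elastic fibre and matrix glycoprotein list did not, and the contractile list passed in addition. Control 3 was the only female array by Xist (11.48 against 5.93 to 6.59 elsewhere) and the Y-linked genes.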

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

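The tests of the hybridisation batch, of embryo sex, of differences between cultures and of the labelling batch, and the count of divisions balanced by batch, were chosen after the results were seen, and the macrophage covariate after seeing the data. Dixon's test marked 17 of 134 groups of 4 arrays with 1 array far from the others, where chance marks about 1 in 20. Of these, 6 were in control 3, 5 in control 4 and 4 in mutant 4, where the mean of macrophage and leukocyte markers was 11.19 against 13.31 in each other mutant.

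Control 3 stood apart on sex-linked genes, with Xist at 11.48 (other controls at most 6.36) and Eif2s3y at 4.62, Kdm5d at 4.26 and Uty at 4.03 (other controls at least 10.68, 8.40 and 8.78). It was also the highest control for Cd200 at 9.78 and Csrp2 at 12.66. Control 1 was the highest control for Mex3b at 10.60. Mutant 4 was the lowest mutant for Cthrc1 at 6.26, the highest for Limch1 at 7.72 and the highest for the mean of BMP signalling genes at 9.65. Mutant 1 had the lowest mutant mean of p53 targets and cell cycle inhibitors, 10.52. Control 4 had the lowest control means of elastic fibre and matrix glycoproteins (10.88), fatty acid and triglyceride synthesis (9.91), WNT signalling (8.38), hedgehog signalling (8.65) and osteoblast genes (7.82).

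Macrophage and leukocyte markers had a median difference of 0.81, and 0 of the 21 stand on another list. Differences in macrophage content between cultures that do not follow the genotype cannot be told apart from a genotype effect, since the list mean gave an exact two-sided permutation p of 0.2 and 4 arrays per group leave it open. Each hybridisation batch held 2 arrays of each genotype, so the batch as a block cannot move the difference. The block left the list past camera (adjusted p = 4.28e-07, and 5.68e-12 to 0.753 over the alternatives), which therefore says little about the batch. Medians of 0.63 and 0.94 within the batches argue against the batch as the whole cause, although the array means overlapped in the second. The sex of control 3 is argued against as the whole cause, because without it the lower quartile of the members was 0.485. A larger macrophage share in most mutant cultures may lie behind the difference, which is a hypothesis, and no sort that would remove such cells is named in the labels. The brightest markers, picked after their values were seen, were Lyz2, Cd52 and Fcer1g, with means over all arrays of 14.81, 14.14 and 13.72. They differed by 0.09, 0.66 and 0.67. Lyz2 lay near the highest value of any probe set (15.18), which limits what its difference can show.

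For the 12 genes that fell, the median with the macrophage mean as a covariate was -1.55, the smallest difference was -0.888 and all 12 passed. These genes were called on the same arrays with no overlap between genotypes, while the macrophage mean did overlap. A gene that followed the macrophage mean could hardly have been called, so this fit does not decide on macrophage content as a cause. With the labelling batch as a block 10 of the 12 calls ended while the differences stayed. The smallest was -1.01, and the median was -1.55 with a median SE of 0.144, against -1.56 and 0.163 without the block. Both labelling batches held arrays of both genotypes, so genes without overlap between genotypes were bound to keep their sign. The block therefore does not decide on that batch as a cause. The calls ended as the residual degrees of freedom went from 6 to 5 and the median unadjusted limma p of the 12 from 1.56e-05 to 4.47e-05. A genotype effect on these genes stays a hypothesis, because other divisions of the arrays gave as many calls.

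Amino acid synthesis and ATF4 target genes had a lower list mean on all 4 mutant arrays than on any control. The nearest were mutant 4 at 10.77 and control 4 at 10.84. With the macrophage mean as a covariate the median was -0.449 and the upper quartile -0.21, against a median of -0.63 without it. The list mean did not overlap between genotypes while the macrophage mean did, so this covariate could hardly remove all of the difference. Only mutant 4 had a macrophage mean (11.19) near those of controls 3 and 4. That fit therefore does not decide on macrophage content as a cause. The hybridisation block again cannot move the difference, and it left the list past camera (adjusted p = 3.11e-08, and 7.6e-11 to 0.753 over the alternatives). Medians of -0.72 and -0.43 within the batches argue against that batch as the whole cause. The gap between the nearest array means of the genotypes was 0.46 in the first batch and 0.07 in the second. Without control 3 the upper quartile was -0.303, which argues against its sex. A genotype effect stays an open hypothesis; media use and cell density of the cultures were not tested.

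Chance could not be excluded for the counts. Of the 35 divisions of the 8 arrays into 4 and 4, 4, the real one included, gave at least its 16 genes, with a highest other count of 548, and 4 gave at least the 16 with a 1.5-fold change, with a highest other of 496. For the 10 gene lists 20 divisions gave as many, with a highest other of 19. The division of mutants 1 to 3 and control 2 against the rest called 548 genes. These 4 arrays had the highest macrophage means, 13.31 in each mutant and 12.72 in control 2, followed by control 1 with 12.50. The first principal component held 55.3% of the variance and read -40.1 to -29.3 in mutants 1 to 3. It read -6.61 in control 2, 0.60 in control 1 and 30.6 to 41.2 in mutant 4 and controls 3 and 4. The division along the hybridisation batch called 137 genes, with 65 by 1.5-fold or more and 6 lists. The arrays thus carry structure besides genotype. With the hybridisation batch as a block 20 genes passed. The 18 divisions with 2 arrays of each hybridisation batch on either side were fitted without that batch as a block. Among them 2 gave at least 16 genes, the real one and that of mutants 1 to 3 and control 4 with 20. For the lists, 10 gave at least 10, so chance could not be excluded there either. With the block only the real division was fitted.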

How the results depend on the processing

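The batch blocks, single batches, averaged pairs and macrophage covariate were chosen after seeing the data; the cause of each difference below was not tested. All 16 called genes kept their sign in every fit, except that the fit with dim genes left out tested 15 of them. Where arrays were left out, averaged or taken by batch this was certain, as the genotypes did not overlap for these genes. Camera's direction was never opposite to the main fit for a list called in the main fit or in the alternative. Median signs could differ: serum and immediate early response read -0.04 in the main fit and 0.12 in the first hybridisation batch, where it passed. Against 16 genes called, and 16 genes called with at least 1.5-fold (in brackets), limma called 3 (3) with the most variable probe set, 1470 (721) with array weights, 0 (0) in the ordinary linear model (2435 at an unadjusted p under 0.05), 2 (2) with the labelling block, 2085 (1268) in the first hybridisation batch, 0 (0) in the second (947 unadjusted), 0 (0) with the closest pairs averaged (1612 unadjusted) and 55 (52) with the macrophage covariate. Tested separately, the probe sets gave 1 call. A threshold of 0.01 gave 0 and of 0.1 gave 41, and treat against 1.2-fold gave 1. Leaving out 1 array gave 0 to 1316 genes, 0 to 947 with 1.5-fold, and 8 to 18 lists, the highest each time without mutant 4. Against 10 lists, 17 passed with array weights, 19 in the first hybridisation batch, 0 with an estimated correlation and 0 in fry. Leaving out dim genes ended 3 of the 10 list calls (elastic fibre and matrix glycoproteins, G2/M and hypoxia), and quantile normalization and median centring each ended the G2/M call.

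With the replicate number as a block 0 genes passed (0 with 1.5-fold, 3828 at an unadjusted p under 0.05) and 10 lists did; the hypoxia call ended (adjusted p = 0.125 for hypoxia-induced genes, from 0.000165 to 0.753 over the alternatives). The deviations of same-numbered arrays correlated at 0.47, 0.42, -0.09 and 0.37 and no mutant array correlated best with its own number, so the numbers were not taken as a pairing. Values past the threshold in neither fit changed sign 57 times among list medians and 2 times for Tgfbr2. The list medians were at most 0.14 in size after the change, which sets no limit on their size in the main fit. For Tgfbr2 the dimmest probe set read -0.05 in the second hybridisation batch and the brightest -0.02 with the macrophage covariate. The sex covariate, the ordinary model for lists, and joined probe sets for Tgfbr2 were not run. The scalings moved the median of all genes by at most 0.04, and dim genes are limited by background: 12187 genes lay above the median probe set, of which 15 passed.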

Other observations

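The hybridisation block was chosen after seeing the data. Signalling lists not described so far did not pass camera, and 0 of their members passed over all genes in limma, where 2826 genes had an unadjusted p under 0.05. WNT genes had a median of -0.14 (35 members, adjusted p = 0.0996). Adjusted over the list alone, Wnt5b, a ligand of noncanonical signalling, fell by 0.98 (SE 0.16, list-adjusted p = 0.0077) and the antagonist gene Dkk2 fell by 1.76 (SE 0.35, list-adjusted p = 0.0164). Among FGF and PDGF genes (29, median -0.22, adjusted p = 0.127) Pdgfc, a growth factor needed for palate closure, fell by 1.47 (SE 0.25, list-adjusted p = 0.00981). BMP genes had a median of -0.07 (26, adjusted p = 0.249), with Bmp2 at -1.62 (SE 0.43) and Id1 at -0.48 (SE 0.13), and hedgehog genes one of -0.22 (14, adjusted p = 0.339), with Smo at -0.59 (SE 0.15); none of these passed adjusted over the list alone. Transcription factors of palatal mesenchyme had a median of -0.09 (37, adjusted p = 0.225), with only Dlx5 past the test adjusted over the list alone (list-adjusted p = 0.00235 in limma).

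Contractile and smooth muscle genes had a median of -0.21 (22 members, camera adjusted p = 0.0746), with 0 past limma over all genes or over the list alone and 1 at an unadjusted p under 0.05. With the hybridisation batch as a block the list of contractile and smooth muscle genes passed (adjusted p = 0.0345, from 0.000885 to 0.867 over its alternatives). The same block brought p53 targets and cell cycle inhibitors (21, median -0.27, adjusted p = 0.116) to adjusted p = 0.0398 (0.00981 to 0.753 over the alternatives). With 1 array left out the median of p53 targets and cell cycle inhibitors ran from -0.38 without control 2 to -0.07 without control 4, and the list passed in none of these fits. Oxidative stress genes had a median of -0.17 (20, adjusted p = 0.516); adjusted over the list alone the cystine transporter gene Slc7a11 fell by 0.72 and Gpx8 fell by 0.50, and the glutathione transferase gene Gsta4 rose by 0.97. Chaperones of the endoplasmic reticulum (22, median -0.09, adjusted p = 0.225), inflammatory cytokines (30, median -0.22, adjusted p = 0.462), immediate early genes (24, median -0.04 with camera direction up, adjusted p = 0.924) and ribosomal proteins (24, median -0.00396, adjusted p = 0.853) did not pass. Among the immediate early genes Zfp36, which destabilises cytokine transcripts, rose by 0.67 (SE 0.15) adjusted over the list alone. The list serum and immediate early response passed in the first hybridisation batch alone (median 0.12, adjusted p = 0.00706, from 0.00706 to 1.00 over the alternatives) and with the macrophage covariate (median 0.19, adjusted p = 0.0474). In the second hybridisation batch alone the median of serum and immediate early response was -0.45 and the list did not pass (adjusted p = 0.581). Without mutant 4 the following lists passed camera, with these medians: WNT signalling -0.26, hedgehog signalling -0.37, FGF and PDGF signalling -0.39, BMP signalling -0.16, contractile and smooth muscle genes -0.29, palatal mesenchyme transcription factors -0.26, and inflammatory cytokines and chemokines -0.60. Without 1 other array these medians came as near to 0 as -0.04 for WNT signalling (control 2), -0.09 for hedgehog signalling (mutant 3), -0.14 for FGF and PDGF signalling (mutant 3), -0.04 for BMP signalling (mutant 2), -0.07 for contractile and smooth muscle genes (control 4), -0.06 for palatal mesenchyme transcription factors (mutant 1) and -0.05 for inflammatory cytokines and chemokines (control 3).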
